A study of Sus scrofa with 8 samples.

How the data were processed

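RNA was measured in left ventricular tissue of 8 pigs, 4 wild type (WT) and 4 gene-edited. Per the labels' protocols, total RNA was extracted with TRIzol, polyadenylated RNA was selected on oligo-dT beads, and libraries were made with random-primed cDNA and an NEBNext Ultra kit. Strand-specific counting is not stated, so reads of a gene and of an overlapping or antisense partner could not be told apart. The protocol text also mentions cardiomyocytes derived from human stem cells, which are not among these 8 samples. Groups were taken from the genotype labels. In 1 of the 4 mutant samples, replicate 4, the genotype label names KCNH3 where the series design names only KCNH2, so the group is called mutant and the gene counts, camera lists, named genes and the KCNH2 test were also computed without that sample. The labels number the pigs separately and give no sex, age, litter, tissue collection time or sequencing batch. Replicate numbers only name libraries, and p-values measure the spread between these samples alone.

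The deposited table holds 1 row per gene symbol, with results of the authors' comparison beside 8 columns of signal per gene. Per the file headers and the values, this signal is a normalized count, meaning a gene's read count divided by 1 size factor per library. Per the submitters' processing notes the tool was DESeq2, with no version. The same notes name the human build GRCh38 although the samples are from pig. The aligner, the counter and the annotation are not given in the sources used here, so no genomic coordinates are printed. The remaining columns are the authors' mean normalized count, log2 fold change with its standard error, Wald score, p-value and adjusted p-value, per the file headers. The direction of that comparison is mutant against WT.

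All values in the 8 columns were whole multiples of what 1 read is worth in their column (100% within a tolerance of 1e-06 reads), so whole reads were recovered by division. Of 14720 rows, 2 are named for an annotation source and not for a gene. They held 0.392% to 0.853% of the reads of a library and were left out. Of the remaining 14718 rows, 14504 matched a pig gene symbol in the reference tables. Recovered depth was 15.9 to 22.4 M reads per library. Shares of reads are given with Wilson 95% intervals, whose half-width was at most 0.0223 percentage points. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Genes with near-identical copies, such as MYH7 and ribosomal protein genes, and the overlapping mitochondrial pairs ATP8 with ATP6 and ND4L with ND4, may share reads, and their values are uncertain to that extent.

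The design chosen before the data were examined called for limma on log2 values where a table holds normalized counts. Genes with a normalized count of at least 10 in at least 4 libraries were kept (11660 genes), values were taken as log2(normalized count + 1), and limma 3.58.1 was fitted with a trended, robust prior in R 4.3.3. Differences on this scale understate the change of low genes. Benjamini-Hochberg adjusted p-values under 0.05 were called. KCNH2 was also tested by an exact two-sided permutation test over all 70 assignments of the 8 libraries, whose smallest possible p is 0.0286. Fixed gene lists, 46 in number, were written before the data were examined, and the 42 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01. Estimated correlations were used beside it, and so was fry, whose p tests whether a list's genes move on balance one way and whose mixed p tests change in either direction. Neither compares a list with other genes. A list score is the mean over members of the log2 value of each gene minus its mean over the 8 libraries.

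Genes named in the text follow a rule set before the data were examined. It took KCNH2 and KCNH3, up to 4 members with the smallest p of each described list, the 5 genes with the highest mean and, where fewer than 10 genes passed, the 10 genes with the smallest p in each direction among those with a mean of at least 50. A part of the rule for the 12 highest and 12 lowest fold changes among called genes found no gene, and after the data were seen it was applied to the calls of the authors' deposited table instead. Genes outside the rule are named as such, and some genes that the rule takes are not reported here.

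Alternatives set beforehand were DESeq2 1.42.0 and edgeR 4.0.16 (quasi-likelihood) on the recovered reads, quantile and TMM rescaling, pseudocounts of 0.5 and 5, no filter and a minimum of 100, a plain prior, a minimum log2 difference of 1, and leaving out each library in turn. Array quality weights, leaving out WT replicates 3 and 4 together, DESeq2 with libraries left out, and Fisher's exact tests of the lists among the authors' calls were added after the data were seen. Adjustment for sex was not run, since the labels give none and both Y-linked genes in the table had reads in all 8 libraries. Of these genes, both outside the naming rule, KDM5D had 32.0 to 288 normalized counts in WT and 22.5 to 42.8 in mutant libraries. ZFY had 378 to 564 and 405 to 504. A difference in sex between the groups is therefore not excluded. On counts simulated with the spread of these libraries, limma recovered 2% of genes changed 2-fold, 50% of those changed 4-fold and 82% of those changed 8-fold. DESeq2 recovered 18%, 86% and 98% and called 0.462% of the unchanged genes. Genes were simulated independently of each other, with the same dispersion in both groups. The real libraries share structure between genes and differ in quality, so these rates may not carry over to them. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.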

Results

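Left ventricular transcriptomes were compared between 4 WT pigs and 4 mutant pigs, of which 3 were labelled with a KCNH2 mutation and 1, mutant replicate 4, with a KCNH3 mutation, although the series design names KCNH2 alone. KCNH2 encodes the pore-forming subunit of the rapid delayed rectifier potassium channel, which repolarizes ventricular myocytes, and its loss of function is an established cause of long QT syndrome. WT libraries held 19.7 ± 2.13 M reads (SD, n = 4; M is the SI prefix mega) and mutant libraries 18.0 ± 2.97 M reads (SD, n = 4). The 13 protein-coding genes of the mitochondrial genome took very different shares of these reads. They made up 33.5%, 31.7%, 87.9% and 65.2% of the reads of WT replicates 1 to 4 and 27.5%, 19.9%, 16.7% and 15.9% of those of mutant replicates 1 to 4. The share was 54.6% ± 27.0 in WT (SD, n = 4) and 19.99% ± 5.27 in mutant libraries (SD, n = 4), with no overlap (exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow). Reads of nuclear genes therefore numbered only 2.53 M in WT replicate 3 and 7.53 M in WT replicate 4, against 11.5 M to 16.2 M in the other libraries. In WT replicate 3, 1 read was worth 4.84 normalized counts, and 10724 genes had a read, against 12881 to 13733 elsewhere. Mutant replicates 3 and 4 were the most similar pair (Spearman's rho across genes 0.991). Their counts differed by more than sampling noise (chi-square per gene 12.8, against 54.4 for mutant replicates 2 and 3, the next closest pair). That argues against the same library counted again but cannot tell separate animals from separate libraries of the same animal. They were counted as separate samples because the labels number the pigs separately.

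**Figure D1:**
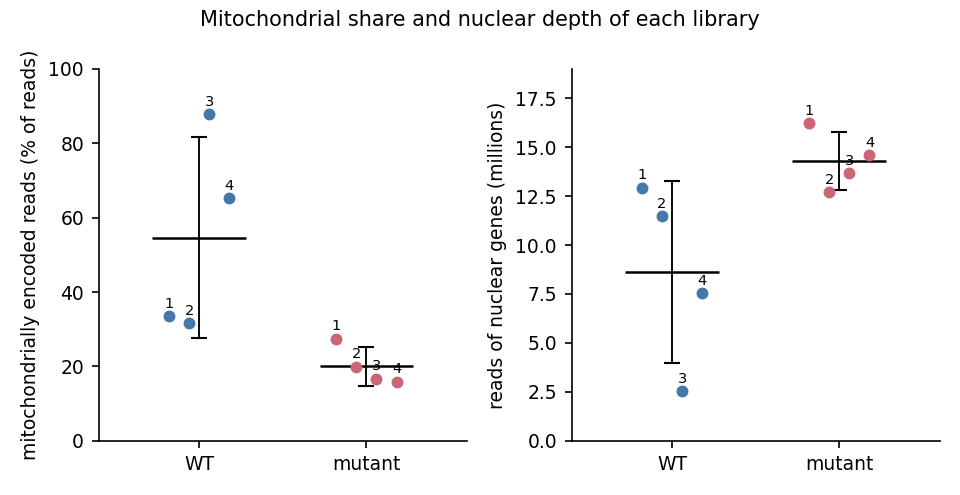
Share of reads from mitochondrially encoded genes (left, percent) and reads of nuclear genes (right, in M reads) in each library, numbered by replicate, with group means (lines) and SD (bars). All 4 WT libraries lie above all 4 mutant libraries in mitochondrial share, and WT replicate 3 has 2.53 M nuclear reads.

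KCNH2 transcripts were present in every library, and their level did not separate the groups. Normalized counts of KCNH2 were 989, 559, 1909 and 148 in WT replicates 1 to 4 and 798, 1762, 1751 and 1839 in mutant replicates 1 to 4. The means were 901 ± 754 in WT (SD, n = 4) and 1538 ± 495 in mutant libraries (SD, n = 4), a log2 difference of 1.21 (exact two-sided permutation p = 0.257; limma adjusted p = 0.438). Without WT replicate 4 the difference was 0.52. The authors' deposited table gives KCNH2 a log2 fold change of 0.78 (adjusted p = 0.547). A gene-level count does not show the edited sequence, so it neither checks nor contradicts the genotype labels. KCNH3, a related channel gene named in the label of mutant replicate 4, had 0, 0, 0 and 5 reads in WT replicates 1 to 4 and 0, 1, 0 and 3 reads in mutant replicates 1 to 4. It fell below the filter, and a count of 0 allows up to 3 reads, or 0.134 to 0.183 reads per M reads in these libraries.

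Of 42 gene lists, 8 passed camera with the preset correlation, and none of the 42 passed with an estimated one (for these 8, adjusted p = 0.159 to 0.867 with an estimated correlation). Lower in mutant left ventricles were 6 of the 8, namely immediate early, mitochondrially encoded, cytosolic ribosomal protein, interferon, inflammatory, and glucocorticoid and stress hormone response genes. Higher were 2, genes of the tricarboxylic acid (TCA) cycle and ketone use, and of sodium channels and gap junctions. With the preset correlation 32 of the 35 splits of the 8 libraries called at least 8 lists. The other 34 lists had adjusted p of 0.117 to 0.996. The median, mean and test differed in sign in 12 of those 34 lists and in 0 of the 8. No single gene passed limma (smallest adjusted p = 0.142), although 1616 of 11660 genes had an unadjusted p under 0.05, 823 higher and 793 lower in mutant libraries. All mutant values lay above all WT values for 719 genes and below them for 609, together 11.4% of the genes tested against 2.86% by chance. The count of single genes differed between tools and with the libraries used. On the recovered reads, edgeR called 0 of 11878 genes (1730 at an unadjusted p under 0.05, 693 higher and 1037 lower) and DESeq2 called 582, 168 higher and 414 lower. The authors' deposited table calls 580 genes, 168 higher and 412 lower, and all 580 were among those 582. Without mutant replicate 3 or 4 the limma count at an unadjusted p under 0.05 was 1035 or 915. With array quality weights limma called 92 genes, and 12 without WT replicates 3 and 4. DESeq2 called 1027 genes without WT replicate 1, and 333, 370, 173 and 128 without mutant replicates 1, 2, 3 and 4. The median log2 difference over all genes was 0.12 in limma, 0.16 after TMM rescaling and -0.03 in DESeq2.

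Immediate early genes, which are transcribed within minutes of a stimulus, were lower as a group in mutant ventricles. Of 28 measured members 26 were lower and 2 higher, with a median log2 difference of -1.52 (camera adjusted p = 4.19e-16; adjusted p = 0.159 with an estimated correlation; fry adjusted p = 0.0257). None passed over all genes in limma, and 17 passed when adjusted over the list alone. The transcription factor MYC had 2033 ± 991 normalized counts in WT and 315 ± 148 in mutant libraries (SD, n = 4), a log2 difference of -2.62 ± 0.47 (SE). The differences were -2.56 ± 0.39 (SE) for MAFF, a small MAF transcription factor, -2.09 ± 0.36 (SE) for ZFP36, which promotes decay of AU-rich mRNAs, and -1.61 ± 0.28 (SE) for the salt-inducible kinase SIK1. For each of these 4 genes every mutant library lay below every WT library. The authors' deposited table calls 16 of 27 members lower and none higher. The list scores were 0.69 ± 0.45 in WT and -0.69 ± 0.28 in mutant libraries (SD, n = 4), without overlap (exact two-sided permutation p = 0.0286, and 0.150 after adjustment over 42 lists). Like the list scores, the mitochondrial share of reads was higher in all 4 WT libraries than in any mutant library.

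Genes of the glucocorticoid and stress hormone response were lower in mutant ventricles in 12 of 15 members, with a median log2 difference of -0.81 (camera adjusted p = 0.000425; adjusted p = 0.741 with an estimated correlation). Members of this list overlap with other lists. DUSP1 is also an immediate early gene and CEBPD is also on the inflammation list. ANGPTL4 is also on the fatty acid use list and DDIT4 on the hypoxia list, so none of these named genes is particular to this response. ANGPTL4, an inhibitor of lipoprotein lipase, had 513 ± 167 normalized counts in WT and 174 ± 38.0 in mutant libraries (SD, n = 4). The phosphatase gene DUSP1 had 4532 ± 1510 and 1665 ± 900 (SD, n = 4). The differences of CEBPD, a stress-induced transcription factor, and DDIT4, an inhibitor of mTORC1 signalling, were -1.87 ± 0.60 (SE) and -0.96 ± 0.34 (SE). Over all genes none passed limma, and 2 passed when adjusted over the list alone. The list's median was -0.53 without WT replicate 4. Without WT replicates 3 and 4 together it was -0.39 and no longer passed (camera adjusted p = 0.0812).

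**Figure D2:**
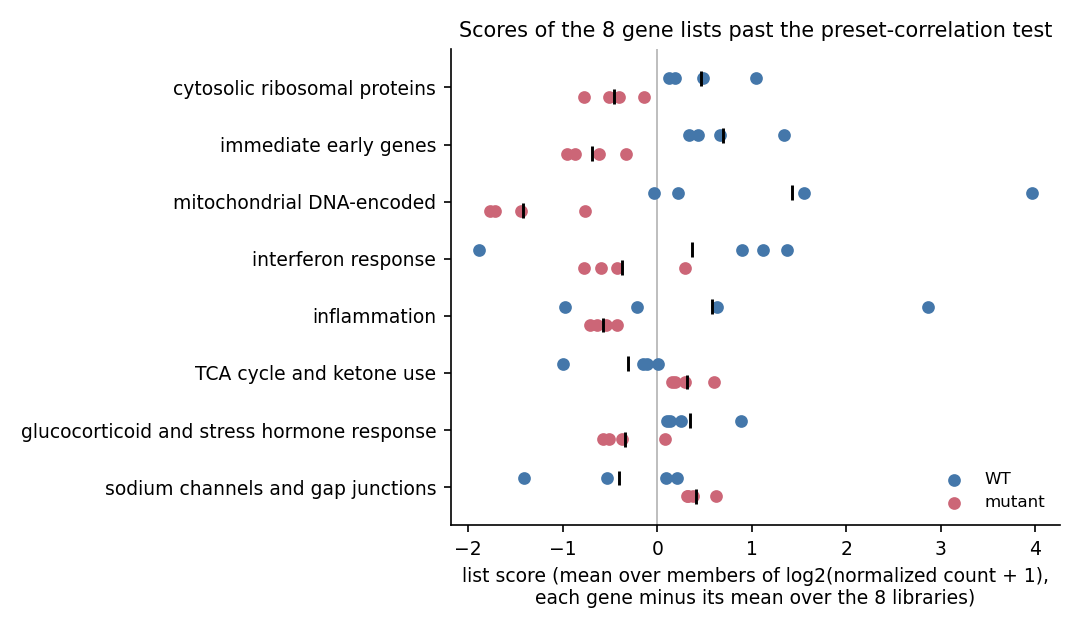
Scores of the 8 lists that passed camera with the preset correlation, 1 point per library, WT above and mutant below, with black ticks at group means; the horizontal axis is in log2 units. Immediate early gene scores average 0.69 in WT and -0.69 in mutant libraries without overlap, whereas interferon and inflammation scores overlap.

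All 13 mitochondrially encoded genes were lower in mutant libraries, although after quantile rescaling COX1 differed by 0 and COX3 by 0.15. The list had a median log2 difference of -2.50 (camera adjusted p = 2.14e-07; adjusted p = 0.867 with an estimated correlation). The cytochrome oxidase subunit gene COX1, the most abundant transcript, differed by -2.50 ± 0.88 (SE), COX2 by -2.80 ± 0.79 (SE), COX3 by -2.38 ± 0.87 (SE), and the ATP synthase subunit gene ATP6 by -2.70 ± 0.91 (SE). The complex I subunit genes ND1 and ND2 differed by -3.44 ± 0.62 (SE) and -3.36 ± 0.88 (SE), and ND4 by -2.05 ± 1.06 (SE). Without WT replicate 3 the differences of COX1, COX3, ATP6 and ND4 were -1.65, -1.54, -1.78 and -0.95. ATP8, whose reading frame overlaps ATP6, had the smallest p of all genes with a mean of at least 50. Its normalized counts were 35710, 24417, 7993 and 1883 in WT replicates 1 to 4 and 152 to 229 in mutant libraries, a difference of -5.90 ± 0.78 (SE; limma adjusted p = 0.142). The authors' deposited table calls all 13 genes lower. No member passed over all genes in limma, and 11 passed when adjusted over the list alone. The median was -1.65 without WT replicate 3 and -0.98 without WT replicates 3 and 4.

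Cytosolic ribosomal protein genes were lower in mutant ventricles in all 44 measured members. The median log2 difference was -0.97 (camera adjusted p = 3.09e-26; adjusted p = 0.846 with an estimated correlation). RPL37 had 11605 ± 3413 normalized counts in WT and 4619 ± 1013 in mutant libraries (SD, n = 4), and RPS19 had 16743 ± 4130 and 7197 ± 1581 (SD, n = 4). RPL22 and RPL38 differed by -1.09 ± 0.26 (SE) and -1.17 ± 0.30 (SE). Every mutant library lay below every WT library in 34 members. None passed over all genes, 37 passed when adjusted over the list alone, and the authors' deposited table calls 21 lower. The WT libraries with the highest mitochondrial shares, replicates 3 and 4, also had the highest ribosomal protein scores, 1.04 and 0.49, and without both the median was -0.63. Mutant libraries did not all follow this order. Mutant replicate 1 had the highest share among them, 27.5%, but the lowest score, -0.78, while the scores of mutant replicates 2 to 4, -0.14, -0.41 and -0.51, fell with their shares.

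Interferon-stimulated genes were lower in mutant ventricles in 26 of 32 members, with a median log2 difference of -0.81 (camera adjusted p = 1.08e-06; adjusted p = 0.867 with an estimated correlation). The ubiquitin-like modifier ISG15 had 586 ± 383 normalized counts in WT and 70.9 ± 15.0 in mutant libraries, and the transcription factor IRF7 had 231 ± 161 and 28.2 ± 7.89 (SD, n = 4). The guanylate-binding protein gene GBP2 and the ISG15 protease gene USP18 differed by -2.05 ± 0.51 (SE) and -1.52 ± 0.44 (SE). WT replicate 3 did not follow the other WT libraries, with a score of -1.89 against 0.90 to 1.37, and without it the median was -1.43. That library also had the fewest reads of nuclear genes, 2.53 M, and an effect of depth on its score was not tested. Inflammatory genes were lower in 22 of 28 members, with a median of -1.29 (camera adjusted p = 1.30e-05; adjusted p = 0.867 with an estimated correlation). The transcription factor CEBPB differed by -1.42 ± 0.36 (SE) and the oncostatin M receptor gene OSMR by -2.07 ± 0.59 (SE). The neutrophil-attracting chemokine CXCL2 had 12567 normalized counts in WT replicate 2, 247 to 461 in the other WT libraries and 20.5 to 86.7 in mutant libraries. Inflammation scores were -0.22, 2.86, -0.98 and 0.63 in WT replicates 1 to 4 and -0.71 to -0.42 in mutant libraries. WT replicate 3 thus lay below every mutant library. WT replicate 2 also had the highest score of the neutrophil marker list, 3.17, and without that library the inflammation median was -0.48. Over all genes no member of either list passed limma, and 3 interferon and 0 inflammation genes passed when adjusted over the list alone.

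TCA cycle and ketone-use genes were higher in mutant ventricles in 21 of 23 members, with a median log2 difference of 0.70 (camera adjusted p = 2.39e-05; adjusted p = 0.867 with an estimated correlation). DLAT, a subunit gene of the pyruvate dehydrogenase complex, had 1964 ± 798 normalized counts in WT and 4446 ± 764 in mutant libraries (SD, n = 4). DLST, of the oxoglutarate dehydrogenase complex, had 2549 ± 996 and 5328 ± 721 (SD, n = 4). The mitochondrial thiolase gene ACAT1 and the aspartate aminotransferase gene GOT1 differed by 0.70 ± 0.22 (SE) and 0.89 ± 0.31 (SE). No member passed in limma, over all genes or when adjusted over the list alone. The authors' deposited table calls 3 members higher, and the median was 0.43 without WT replicate 4 and 0.38 without WT replicates 3 and 4. Nuclear genes of oxidative phosphorylation, in contrast, had a median of 0.22 with 38 members higher and 19 lower (camera adjusted p = 0.620), although without WT replicate 1 it passed at 0.44 (camera adjusted p = 0.00647; adjusted p = 0.892 with an estimated correlation), and the median was 0.12 without WT replicate 3 and -0.05 without WT replicate 4. Without WT replicates 3 and 4 it was called in the opposite direction (median -0.18, camera adjusted p = 0.0489; adjusted p = 0.856 with an estimated correlation).

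**Figure D3:**
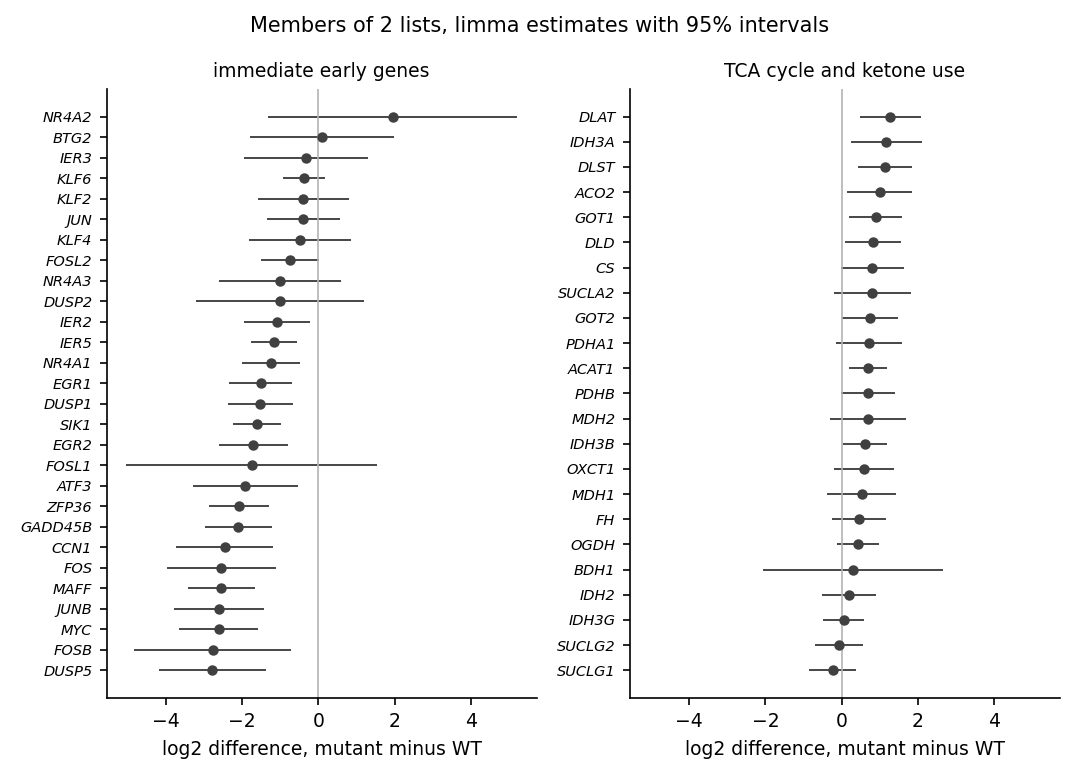
Log2 differences (mutant minus WT) of each member of the immediate early gene list and the TCA cycle and ketone-use list, with 95% limma intervals. Of the immediate early genes 26 of 28 lie below 0, and of the TCA cycle and ketone-use genes 21 of 23 lie above 0.

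Sodium channel and gap junction genes were higher in 19 of 22 members, with a median log2 difference of 0.87 (camera adjusted p = 0.0160; adjusted p = 0.867 with an estimated correlation). The desmosomal genes DSP and PKP2, which anchor myocytes to each other, had log2 differences of 1.62 ± 0.41 (SE) and 1.06 ± 0.33 (SE), and the junction scaffold gene TJP1 one of 0.78 ± 0.26 (SE). The connexin gene GJC1 went the other way, at -1.12 ± 0.30 (SE). None of these passed over all genes, and 2 members passed when adjusted over the list alone. The list no longer passed without WT replicate 3 (median 0.57, adjusted p = 0.107), without WT replicate 4 (median 0.71, adjusted p = 0.0685) or without both (median 0.34, adjusted p = 0.389). Both libraries had low scores, -1.41 and -0.53, and the 2 highest mitochondrial shares.

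Potassium channel genes did not pass as a list (17 of 22 members higher, median 0.81, camera adjusted p = 0.117), and without WT replicate 3 the median was 0.23 (adjusted p = 0.388). Within it, KCNJ2, which encodes the main inward rectifier of ventricular myocytes, had 365 ± 263 normalized counts in WT and 1241 ± 330 in mutant libraries (SD, n = 4). KCNJ5 and KCNJ3, the subunits of the acetylcholine-activated channel, had log2 differences of 1.78 ± 0.41 (SE) and 2.44 ± 0.90 (SE), and that of KCNJ3 was 1.41 without WT replicate 4. Calcium handling genes were also not called as a list (19 of 28 members higher, median 0.30, or 0.54 without WT replicate 1 and 0.45 without WT replicate 2, camera adjusted p = 0.284). The ryanodine receptor gene RYR2, which releases calcium from the sarcoplasmic reticulum, had 5789 ± 2479 normalized counts in WT and 20864 ± 10037 in mutant libraries (SD, n = 4). The calcium channel subunit gene CACNA2D1 had 1009 ± 318 and 2188 ± 325 (SD, n = 4). The pore-forming subunit gene CACNA1C and the sodium-calcium exchanger gene SLC8A1 had overlapping groups, with log2 differences of 0.83 ± 0.29 (SE) and 1.66 ± 0.58 (SE). In the sarcomere list (18 of 26 higher, camera adjusted p = 0.404), the β-myosin heavy chain gene MYH7 had 127942 ± 22310 and 256660 ± 34038 normalized counts (SD, n = 4). MYOM1, a gene of the sarcomere's M-band, had 4812 ± 1553 and 10270 ± 417 (SD, n = 4), and FLNC had a log2 difference of 1.12 ± 0.41 (SE), which was 0.70 without WT replicate 4. The authors' deposited table calls KCNJ2, KCNJ5, RYR2, CACNA2D1, DSP, MYH7 and MYOM1 higher and GJC1 lower. None of these genes passed limma.

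**Figure D4:**
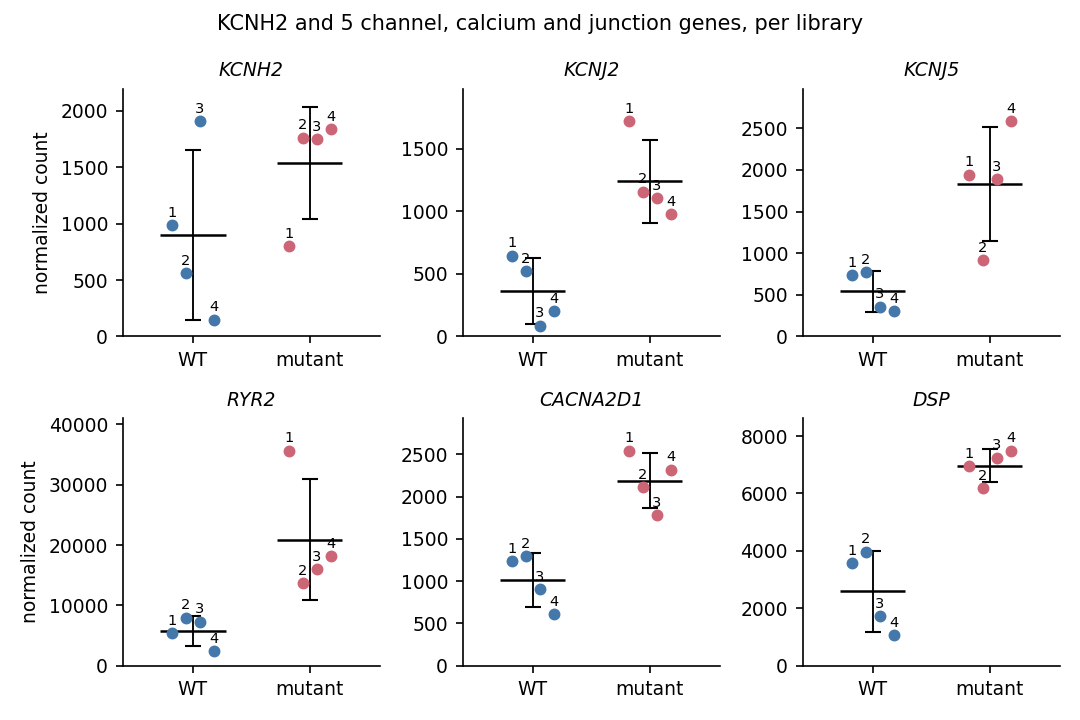
Normalized counts of KCNH2, KCNJ2, KCNJ5, RYR2, CACNA2D1 and DSP in each library, numbered by replicate, with group means (lines) and SD (bars). KCNH2 overlaps between groups, with WT at 148 to 1909 and mutant at 798 to 1839, while the other 5 genes do not.

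The genes with the smallest p in limma had groups that did not overlap, but none passed. Among those higher in mutant libraries, the epoxide hydrolase gene EPHX1 had 173 ± 77.1 normalized counts in WT and 1022 ± 351 in mutant libraries, and the glutamate transporter gene SLC1A3 had 51.2 ± 19.7 and 221 ± 26.7 (SD, n = 4). The actin-organizing gene RFLNB and the α1-adrenergic receptor gene ADRA1D differed by 2.87 ± 0.49 (SE) and 3.40 ± 0.64 (SE). PDPR, a regulator of pyruvate dehydrogenase phosphatase, the phospholipase gene PLA2G4A and RETSAT, a retinol saturase, lay at 1.48 to 1.75. Among those lower, the stress-response gene GADD45G had 4029 ± 2091 and 657 ± 152, and the RNA helicase gene MOV10 566 ± 48.6 and 228 ± 16.7 (SD, n = 4). The arginase gene ARG1 differed by -3.36 ± 0.53 (SE). The endothelin receptor gene EDNRB, the endothelial gene APOLD1, the synuclein gene SNCG and the transcription factor CSRNP1 differed by -1.94, -2.10, -2.29 and -1.92. The limma adjusted p of these genes was 0.142 to 0.164, and each is called in the authors' deposited table in the same direction.

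With all 8 libraries no marker list of a cell type was called. The cardiomyocyte list had a median log2 difference of 0.27 (camera adjusted p = 0.620), the fibroblast list 0.17 (0.749), the endothelial list 0.19 (0.749, with the test towards lower), the macrophage and monocyte list 0.42 (0.542) and the neutrophil list -0.75 (0.451). Single libraries decided the size of all 5 medians and the direction of 3. The cardiomyocyte median was 0.05 without mutant replicate 1, 0.09 without WT replicate 4 and 0.14 without WT replicate 2. The fibroblast median was -0.13 without WT replicate 2, 0.42 without WT replicate 1 or mutant replicate 2, and 0.64 without WT replicate 3. The endothelial median was -0.08 without WT replicate 2, -0.03 without WT replicate 3, 0.07 without mutant replicate 1, and 0.68 without WT replicate 4, with the test then towards higher. The macrophage and monocyte median was 0.07 without WT replicate 1, with the test then towards lower, 0.20 without WT replicate 3, 0.21 without mutant replicate 2 and 0.68 without mutant replicate 4. The neutrophil median was 0.12 without WT replicate 2, 0.05 without mutant replicate 1 and -1.34 without WT replicate 1. These values exclude neither equal nor different cell composition, since estimated correlations within the lists reached 0.50 for endothelial and 0.42 for neutrophil genes. Erythroid genes had a median of -0.97 (camera adjusted p = 0.453) and a score of -4.93 in WT replicate 4, against 1.57 to 2.72 in the other WT libraries, and the median was -0.22, -0.23 and -0.48 without WT replicates 1, 2 and 3. Without WT replicate 4 the erythroid list was called lower (median -2.59, camera adjusted p = 6.37e-09; adjusted p = 0.0979 with an estimated correlation) and the macrophage and monocyte list higher (median 0.84, camera adjusted p = 0.0179; adjusted p = 0.803 with an estimated correlation). Without WT replicates 3 and 4 both were called again, at medians of -2.93 (camera adjusted p = 1.28e-09; adjusted p = 0.163 with an estimated correlation) and 1.09 (camera adjusted p = 0.000176; adjusted p = 0.750 with an estimated correlation).

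Gene by gene, the limma differences and those of the authors' deposited table ranked genes alike (Spearman's rho 0.893 across genes, which are not independent replicates). Of the authors' 580 calls 544 were tested in limma, all in the same direction and 527 with an unadjusted p under 0.05. None was called by both at adjusted p under 0.05. Both sets of values come from the same 8 libraries, so this is a comparison of methods and not a replication. Among the authors' calls with non-overlapping groups and a mean of at least 50 (416 genes), the highest fold changes included CEL, a bile salt-stimulated lipase gene, at 4.63, the T cell co-stimulatory receptor gene TNFRSF9 at 3.53 and the metalloproteinase inhibitor gene TIMP4 at 2.34, on the log2 scale. The lowest included ATP8 at -6.60, GNAT1, a transducin gene, at -3.63, and ARG1 at -3.61.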

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

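All values in this part come from a check within each group of 4 libraries for a library whose gap to its nearest neighbour takes up most of the group's range. The check was applied to depth measures, list scores and named genes, 274 times in all, and picked out 19. Chance picks about 1 in 20, which would be 13.7. Since named genes were chosen partly for differing, and lists share genes, the 19 are not independent.

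In WT replicate 4, the β-globin gene HBB had 38.8 normalized counts against 15405 to 27594 in the other WT libraries, and the globin gene HBM had 0 against 456 to 557. Its erythroid marker score was -4.93 against 1.57 to 2.72. The same library had 3518 normalized counts of the filamin gene FLNC against 10637 to 12358, and a TCA cycle and ketone-use score of -0.99 against -0.16 to 0.00. WT replicate 3, the library with the fewest reads of nuclear genes, had an interferon score of -1.89 against 0.90 to 1.37. It had 7165 normalized counts of GADD45G against 2905 to 3032. WT replicate 2 had 12567 normalized counts of CXCL2 against 247 to 461 and 2507 of EDNRB against 955 to 1109.

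Among mutant libraries, replicate 1 stood apart most often. Its KCNH2 level was 798 normalized counts against 1751 to 1839 in the other mutant libraries. Its calcium handling score was 0.50 against 0.03 to 0.08, its glycolysis and glucose uptake score -0.31 against 0.16 to 0.23, and its endothelial marker score 0.34 against -0.14 to -0.08. It had 1423 normalized counts of the integrin gene ITGB6 against 602 to 642, 3569 of TJP1 against 2199 to 2345, 47.6 of SNCG against 55.6 to 57.2, and 4.28 of GNAT1, a transducin gene, against 19.9 to 23.6. Mutant replicate 2 had 3305 normalized counts of DLAT against 4757 to 4928. Mutant replicate 3 had a fatty acid use score of 0.0114 against 0.27 to 0.29.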

How the results depend on the processing

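The tests with array quality weights, without WT replicates 3 and 4 together, and with DESeq2 on fewer libraries were chosen after the data were seen. limma called 0 genes as reported, and also with edgeR in its place, both other pseudocounts, both other filters, TMM rescaling, the plain prior and the fold minimum. DESeq2 called 582. Quantile rescaling called 1 (ND1), array quality weights 92 (30 higher), and leaving out WT replicates 3 and 4 together 12 (2 higher), or 698 in DESeq2. Leaving out 1 library gave 0 to 3 calls in limma (MAP3K8, outside the naming rule, without WT replicate 1; ATP8, HBB and HBM without WT replicate 4) and in DESeq2 1027, 705, 591 and 510 without WT replicates 1 to 4 and 333, 370, 173 and 128 without mutant replicates 1 to 4, so 0 to 1027 over both tools. The cause of the difference between tools was not tested. The 8 called lists became 0 with an estimated correlation and 1 with fry (immediate early genes), and 0 and 3 (2 of the 8 among them) when WT replicates 3 and 4 were also left out. Under the other settings 8 to 12 lists were called, and 8 to 10 without 1 library, but not always the same ones. Sodium channel and gap junction genes were lost with array quality weights (12 lists called, 7 of the 8 among them), without WT replicate 3 (8, 7 of them shared) and without WT replicate 4 (10, 7 shared), and together with glucocorticoid response genes without both (12, 6 shared). Calls added by leaving out 1 library included fatty acid use (without WT replicate 1) and antigen presentation (without WT replicate 3 or mutant replicate 1), with adjusted p = 0.717 to 0.878 with an estimated correlation. The KCNH2 difference kept its direction under all 13 alternatives and passed under none, ranging from 0.52 to 1.75 without 1 library. Of the named genes only COX1 (0) and COX3 (0.15) lost their direction, under quantile rescaling, which sets the top-ranked genes of all libraries to nearly equal values. The 8 called lists kept their direction under the alternatives, 134 times still past the threshold and 34 times not. Adjustment for sex was not run. No paired analysis was possible because the labels give no replicate numbers shared between groups. Depth limits WT replicate 3 most, with 2.53 M nuclear reads.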

Other observations

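The Fisher's exact tests, the tests on WT replicates 3 and 4, the count of limma calls over splits, and the comparison of 5 of the 11 cell-type lists with the immediate early genes were chosen after the results were seen. Clock genes moved in both directions. Of 20 members 8 passed limma when adjusted over the list alone and none over all genes, while camera, which asks for 1 direction, gave an adjusted p of 0.404. fry's test for change in either direction gave 0.000451. TEF, an output transcription factor of the clock, had 315 ± 41.7 normalized counts in WT and 695 ± 173 in mutant libraries (SD, n = 4). The repressors CRY1, BHLHE40 and NFIL3 had log2 differences of -1.04 ± 0.28 (SE), -1.11 ± 0.22 (SE) and -2.06 ± 0.49 (SE). For all 4 genes the groups did not overlap. The labels give no time of tissue collection. In the unfolded protein and amino acid stress list (camera adjusted p = 0.745), the asparagine synthetase gene ASNS was at 173 ± 83.3 and 788 ± 373 normalized counts, whereas ATF4, a transcription factor known to induce it, was at 7200 ± 3867 and 2338 ± 448 (SD, n = 4).

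Matrix genes gave no call as a list (camera adjusted p = 0.621, towards lower, with a positive median of 0.17), although without WT replicate 4 it was called lower (median -0.12, camera adjusted p = 0.0179; adjusted p = 0.929 with an estimated correlation). The median was -0.17 without WT replicate 2 and 0.02 without mutant replicate 4, and without WT replicate 3 it was 0.61 with the test towards higher (camera adjusted p = 0.18), so the list has no settled direction. The matricellular gene CCN1 had a log2 difference of -2.46 ± 0.57 (SE), the metalloproteinase inhibitor gene TIMP1 one of -1.99 ± 0.70 (SE) and TGFB3 one of -0.80 ± 0.29 (SE). TIMP1 was highest in WT replicate 2, at 5992 normalized counts, and its difference was -1.20 without that library. Erythroid genes divided the WT libraries. Without WT replicate 4 their median difference was -2.59 (camera adjusted p = 6.37e-09; adjusted p = 0.0979 with an estimated correlation), and HBB and HBM then passed limma. HBB was at 15405 to 27594 normalized counts in the other 3 WT libraries and 2086 to 2542 in mutant libraries. Of the fixed lists, the mitochondrial (13 of 13), ribosomal protein (21 of 44) and immediate early (16 of 27) lists were the most enriched among the authors' lower calls (Fisher's exact adjusted p = 1.44e-18, 1.44e-18 and 2.75e-16), a test that treats genes as independent.

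The number of genes called in DESeq2 is a first pattern. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, reached 582 genes, and the highest other reached 195. At an unadjusted p under 0.05 in limma the real split was again the only 1 of 35, with 1616 genes against 1147. Being the only 1 of 35 is the strongest result these splits allow. It speaks only weakly against a chance division of the libraries and does not exclude one, and both counts come from the same 8 libraries. Mutant replicates 3 and 4 were the most similar pair. In DESeq2 the other splits with the most calls (195, 193, 121, 112, 82 and 73) all kept that pair on 1 side. Splits that part the pair are thus not fully comparable with the real one, so 1 of 35 overstates the evidence. A technical difference that follows the genotype is not excluded either. For adjusted calls in limma 35 of 35 splits gave as many, since all gave 0, and for lists in camera 32 of 35 did (8 in the real split, 21 in the highest other), so the number of called lists does not exceed chance and the libraries share structure other than genotype.

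The mitochondrial share is the next pattern. The list's mean difference without WT replicates 3 and 4 was -1.51 ± 0.26 (SE), against -2.85 with all libraries. Its median was -0.98 against -2.50, and ATP8, at -7.37, pulled the mean down. These 2 libraries are thus not the whole cause, though the difference was smaller without them. Since the mitochondrial shares of WT replicates 1 and 2 already lay above all mutant shares, a lower value in mutant libraries was to be foreseen. A single factor acting on all mitochondrial transcripts, such as a different yield of mitochondrial RNA, predicts equal differences across genes. Of 13 genes 2 departed from the median difference by more than 3 standard errors, between the bounds set beforehand, so this cannot be told apart from gene-specific change with 4 libraries a group. Genotype, tissue handling and RNA integrity stay open as untested.

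The immediate early genes, another pattern, had their lowest WT scores in replicates 3 and 4 (0.43 and 0.33, against 0.67 and 1.34), so leaving these out could only widen the mean difference, to -1.70 ± 0.37 (SE), and does not test the pattern further. Fewer cells of another type in the mutant tissue would lower that type's markers as far. Of 11 marker lists of other cell types, 9 lay above the immediate early genes by 2.13 to 5.44 standard errors of the gap. The erythroid list lay above by only 0.302 standard errors (gap 0.52 ± 1.70, SE) and the neutrophil list by 0.558 (gap 0.69 ± 1.25, SE), and as both vary widely between the 4 libraries of a group, with the neutrophil median at 0.12 without WT replicate 2, a lower share of either cell type cannot be told apart from a change within cells. Genotype and the interval between death and freezing of the tissue, for which the labels give no values, stay open as untested.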
